A study of Rattus norvegicus with 19 samples.

How the data were processed

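Gene expression was measured in the somatosensory cortex of adult male Wistar rats after the cortex had been perfused with artificial cerebrospinal fluid containing 1 of several agents. Per the labels, total RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised to Affymetrix arrays. The probe set identifiers are those of the Rat Genome 230 2.0 array. The deposited values are log2 probe set signals, which the authors made with GCRMA per the submitters' processing notes; the GCRMA version was not given in the sources used here. GCRMA corrects for background, normalises by quantiles and summarises the probes of a probe set. The 19 arrays fall into set 1 (10 arrays) and set 2 (9 arrays), and the quartiles were nearly equal within a set. Between the sets the median and the upper quartile differed, while the lower quartile was alike. Comparisons of expression in the report were therefore made within a set. Some passages of the Results and the closing section set differences from sham in one set against those in the other. Among the alternatives, 1 adds the shams of set 2 to set 1 and 1 fits all 19 arrays with a term for the set. The number of arrays limits the precision of every value.

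Of 31099 probe sets, 57 were Affymetrix controls, 20843 named 1 gene, 425 named several and 9831 named none. Symbols were matched to the rat gene table of assembly GRCr8 by Entrez identifier for 20764 probe sets and by accession for 3, while 76 kept the symbol of the platform table. Each of the 14226 genes was represented by the probe set with the highest mean over the 19 arrays among those naming it alone, and 4529 genes had more than 1 such probe set. A gene was tested where its log2 value was above 4 on at least 2 arrays of the set, which left 10334 genes in set 2, 10023 in set 1 and 9846 in both. Probe sets with several genes or none were left out of the comparisons of genes.

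Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), two-sided, with Benjamini-Hochberg adjustment over all genes tested and an adjusted p under 0.05 as the threshold. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Set 2 was fitted with its 3 groups sharing 1 estimate of the spread, since the sham group had 2 arrays. Set 1 had 1 array per treatment and time, so an additive model of treatment and time was used and its residual served as the spread. For treatment against sham, the mean of a treatment's 3 arrays was compared with the lone sham array, which was assumed to vary like the treated arrays. Times and treatments were compared among the 9 treated arrays alone, where 7 h and 8 h counted as the early time. SE is the moderated standard error of a log2 difference, and SD is the standard deviation between arrays.

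Before the data were examined, the comparisons, alternatives, gene lists and the rule for naming genes were fixed. The 22 lists were TGF-beta signalling and targets; reactive astrocyte; astrocyte potassium, water and glutamate handling; microglia and macrophage; neutrophil and lymphocyte; cytokine, chemokine and NF-kappaB; complement; interferon response and antigen presentation; glutamate receptors and excitatory synapse; GABA signalling and interneuron; voltage-gated and HCN channels; neuron; oligodendrocyte and precursor; endothelium and pericyte; extracellular matrix; immediate early and activity; cell cycle; heat shock, metallothionein and hypoxia; and 4 lists for dissection and blood, namely choroid plexus, meninges, red cell and striatum. Some genes stand on more than 1 list. Each list was tested with limma's camera at its preset correlation of 0.01, which compares the list with all other genes, and again with an estimated correlation, adjusted over the lists of a comparison. Members were counted at an adjusted p under 0.05 over all genes and again adjusted over the list alone.

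The genes named for a comparison were the 8 largest rises and 8 largest falls past the threshold whose arrays did not overlap between groups, or the 4 smallest p in each direction where none passed. Up to 3 members of each list with the smallest p were added. In comparisons with sham and with the blockers, 16 genes were added, of which Tgfbr2 had no probe set naming it alone and Kcnj10 did not pass the filter in set 1. For single arrays of set 1, the 5 genes per direction with the largest difference from sham at the weakest of the 3 times were named. Other genes are said to have been chosen after their values were seen.

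Genes at least 2-fold higher or lower on the set 1 albumin array at 24 h than on the set 1 sham were tested as lists in set 2 with limma's fry and, on the mean per array, with an exact two-sided permutation test. Correlations of log2 differences across genes were described, not tested, because genes are not independent replicates. Where both sides of a correlation shared arrays, unchanged groups were simulated around those arrays in 100 draws. The tests were also run on simulated data with 200 changed genes added. There, 4-fold changes were recovered at 90 to 100% in every comparison. Recovery of 2-fold changes was 22 to 38% against the lone sham of set 1 and 62 to 82% in the others. The simulated noise was independent between genes, without deviations that many genes of an array share. These rates may therefore be too high for the real data, where some differences above 4-fold did not pass. A comparison without passing genes does not exclude such changes.

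The alternatives were no filter, a filter on a mean log2 above 5, repeated quantile normalisation, a median shift, the mean of a gene's probe sets, all probe sets, an intensity trend with a robust prior, a 2-fold minimum, an adjusted p under 0.1, a replicate block, only the arrays of the groups compared, 1 fit over the 19 arrays, no time term, the set 2 shams added to set 1, each array left out in turn, other entry rules for the set 1 lists at 1.5-fold and 4-fold, and correlations over genes with a mean log2 above 7. List tests with each array of set 2 left out in turn were added after the data had been seen.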

Results

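Log2 expression of 14226 genes was read on 19 arrays of rat somatosensory cortex. In set 1, a single sample was taken for each agent and time, so there were no replicates. Sodium deoxycholate (DOC, 2 mM), a bile salt that opens the blood-brain barrier, was sampled at 7, 24 and 48 h. Bovine serum albumin (0.1 mM), the serum protein, and the cytokine TGF-β1 (10 ng/ml) were sampled at 8, 24 and 48 h, and a sham operation at 24 h. In set 2, all samples were taken at 24 h, from separate animals per the design text: 3 with albumin, 4 with albumin plus blockers of TGF-β receptors, and 2 sham. The blockers were an antibody to TGF-β receptor type 2 (50 µg/ml) and SB431542 (100 µM), an inhibitor of the type 1 receptor kinase. The series asks how albumin and TGF-β1 relate to opening of the blood-brain barrier and to epilepsy arising in the cortex. Array medians were 5.09 to 5.17 in set 1 and 6.05 to 6.18 in set 2. Albumin replicate 2 of set 2 stood apart, with a median correlation of 0.981 with the other arrays of its set, while the other 8 had 0.992 to 0.995. The number of arrays limits the precision.

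The first question was what albumin changed after 24 h in set 2. Genes of inflammation were among the largest rises. Ccl2, a chemokine that attracts monocytes, rose by 8.48 ± 1.04 on the log2 scale (SE, n = 3 against 2; adjusted p = 0.0266). The neutrophil chemokine Cxcl1 rose by 4.28 ± 0.68 (adjusted p = 0.044), and Zfp36, which destabilises cytokine mRNAs, by 3.88 ± 0.59 (adjusted p = 0.0419). The transcription factor Stat3 rose by 2.65 ± 0.44 (adjusted p = 0.044) and its feedback inhibitor Socs3 by 4.01 ± 0.71 (adjusted p = 0.047). Tnfrsf12a, the receptor of the cytokine TWEAK, rose by 4.86 ± 0.87, and Lgals3, a galectin of activated phagocytes, by 4.04 ± 0.65. The stress response gene Gadd45g rose by 3.97 ± 0.73 and Pik3r1, a regulatory subunit of PI3 kinase, by 4.51 ± 0.74 (adjusted p of these 4 genes 0.044 to 0.0487). The largest falls were in Ogn, a small leucine-rich matrix protein (−5.39 ± 0.96, adjusted p = 0.047), in Lbp, which binds lipopolysaccharide (−5.21 ± 0.96, adjusted p = 0.0487), and Coch (−4.14 ± 0.68, adjusted p = 0.044). Falls were also found in Ddc, an enzyme of monoamine synthesis (−3.95 ± 0.43, adjusted p = 0.025), and the sulfate transporter Slc13a4 (−3.89 ± 0.69, adjusted p = 0.047). Fam180a (−3.00 ± 0.54), Ptgds, the prostaglandin D synthase (−2.46 ± 0.39), and Cdkl4 (−2.38 ± 0.40) also fell. Ptgds stands on the meninges list, which was lower in this group (median −1.84). A different share of meningeal tissue between samples remains a candidate for that list. Whether the other falls belong to the same pattern was not tested. In all, 137 of 10334 genes passed, 99 higher and 38 lower, and 87 of them changed at least 2-fold. The sham signals of Ccl2 (3.62), Socs3 (2.34) and Cxcl1 (2.51) lay below the log2 value of 4 used as the filter.

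Of the 23 measured genes of reactive astrocytes, the glial cells that respond to injury, 7 rose and 16 did not pass; 16 rose adjusted over the list alone, and all 23 were above sham. Examples were the cytoskeletal gene Vim (1.47 ± 0.21, adjusted p = 0.0366) and S100a10 (1.59 ± 0.21, adjusted p = 0.0316), while Gfap, the classic astrocyte filament, had 1.27 ± 0.34 (adjusted p = 0.0971). The list was higher than other genes, with a median log2 of 2.18 (camera adjusted p = 1.08e-11), a call lost at an adjusted p = 0.378 with an estimated correlation. Of 31 cytokine, chemokine and NF-kappaB genes, 5 rose, 20 rose adjusted over the list alone, and the median was 1.78 (adjusted p = 1.49e-11; adjusted p = 0.378 with an estimated correlation). It was 1.12 without albumin replicate 3 (adjusted p = 7.48e-08). Besides Ccl2 and Cxcl1, the shared cytokine receptor Il6st rose (0.79 ± 0.14, adjusted p = 0.0459), while Il6 had 1.78 ± 0.76 (adjusted p = 0.227) and Il1b 2.78 ± 1.43 (adjusted p = 0.298). Of 27 heat shock, metallothionein and hypoxia genes, 2 rose, Gadd45g and Gadd45a (2.74 ± 0.47, adjusted p = 0.0455). In that list 13 rose and 1 fell adjusted over the list alone, and the median was 0.76 (adjusted p = 4.26e-05; adjusted p = 0.405 with an estimated correlation). Of 28 immediate early and activity genes, 2 rose, namely Klf6 (1.52 ± 0.19, adjusted p = 0.0266) and Myc (3.53 ± 0.62, adjusted p = 0.047). The list mixes genes of neuronal activity with genes that answer many stimuli, so it is not a measure of neuronal firing. With adjustment over the list alone, 6 rose and 1 fell, with a median of 1.10 (adjusted p = 0.000333; adjusted p = 0.481 with an estimated correlation). Without albumin replicate 2, the median of that list was 0.46 (adjusted p = 0.00286), and its score was 2.12 above sham in that array against 0.28 and 1.41 in the others.

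Of the 26 genes of TGF-beta signalling and targets, 2 rose, namely the co-receptor Eng (1.26 ± 0.23, adjusted p = 0.0486) and the corepressor Tgif1 (1.45 ± 0.27, adjusted p = 0.0495). On adjustment over this list alone, 4 rose. Tgfb2 had 1.54 ± 0.33 (adjusted p = 0.062) and Tgfb1 0.81 ± 0.56 (adjusted p = 0.42). The inhibitory Smad7 had 0.32 ± 0.19 (adjusted p = 0.358), Smad3 −0.15 ± 0.42 (adjusted p = 0.851) and Tgfbr1 −0.28 ± 0.37 (adjusted p = 0.661). The list median was 0.57 (adjusted p = 0.000615; adjusted p = 0.405 with an estimated correlation), and 0.26 without albumin replicate 2. None of the 19 genes with which astrocytes handle potassium, water and glutamate passed over all genes, but 10 fell adjusted over the list alone and 18 were below sham. Gjb6, a connexin of astrocyte gap junctions, had −2.44 ± 0.59 (adjusted p = 0.078), and Gja1 −0.69 ± 0.18 (adjusted p = 0.0932). The potassium channel Kcnj10 had −0.53 ± 0.56 (adjusted p = 0.586) and the water channel Aqp4 −0.30 ± 0.15 (adjusted p = 0.284). The glutamate transporters Slc1a3 and Slc1a2 had −0.37 ± 0.13 (adjusted p = 0.163) and 0.23 ± 0.23 (adjusted p = 0.565). This list had a median of −0.61 (adjusted p = 4.64e-07; adjusted p = 0.405 with an estimated correlation). Without albumin replicate 2 the median was −0.39, and the score of that array was −1.20 against −0.38 and −0.46 in the other albumin arrays.

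Meningeal markers moved with the albumin group. Of 12 such genes, 1 fell, Ptgds, and 9 fell adjusted over the list alone. The collagen Col3a1 had −2.81 ± 0.57 (adjusted p = 0.0569) and the organic anion transporter Slc22a8 −3.38 ± 0.72 (adjusted p = 0.062). Their median was −1.84 (adjusted p = 4.64e-07; adjusted p = 0.387 with an estimated correlation), with a score of −1.44, −2.17 and −1.31 in the albumin arrays. Of 36 extracellular matrix genes, 1 rose, the basement membrane collagen Col4a1 (2.29 ± 0.39, adjusted p = 0.0451), and 1 fell, Hapln1 of perineuronal nets (−1.57 ± 0.25, adjusted p = 0.044). When adjustment was over the list alone, 9 rose and 6 fell (median 0.27, adjusted p = 0.215). Among 20 microglia and macrophage genes, Gpnmb rose (3.39 ± 0.62, adjusted p = 0.0486) while P2ry12, a receptor of resting microglia, had −2.38 ± 0.47 (adjusted p = 0.0558). Here 10 rose and 2 fell adjusted over the list alone (median 0.93, adjusted p = 0.191; the list passed without sham replicate 2, at 1.42 and adjusted p = 0.00177). Eng was the 1 of 23 endothelium and pericyte genes to pass, and 5 rose and 5 fell adjusted over the list alone (median 0.09, adjusted p = 0.717). The drug efflux pump Abcb1a had −1.31 ± 0.26 (adjusted p = 0.0551).

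Neuronal lists had small differences. Of 40 voltage-gated and HCN channel genes, Kcnip1, a subunit of potassium channels, fell (−0.88 ± 0.16, adjusted p = 0.0488), also adjusted over the list alone. The list median was −0.26 (adjusted p = 0.0129; adjusted p = 0.481 with an estimated correlation). None of 34 glutamate receptor and excitatory synapse genes passed over all genes or adjusted over the list alone (median −0.23, adjusted p = 0.0144; adjusted p = 0.481 with an estimated correlation). The same held for 20 oligodendrocyte and precursor genes (median −0.30, adjusted p = 0.0138; adjusted p = 0.564 with an estimated correlation). These 3 calls ended without albumin replicate 2, with medians of −0.08, −0.07 and −0.15 (adjusted p of 0.0674, 0.0545 and 0.108). The oligodendrocyte call also ended without albumin replicate 3 (adjusted p = 0.0842), and without albumin replicate 1 its median was −0.49 and that of the glutamate receptor list −0.35. None of 24 neuron genes (median −0.12, adjusted p = 0.133) or 26 GABA signalling and interneuron genes (median −0.13, adjusted p = 0.133) passed over all genes. Adjusted over the list alone, 0 of the former passed and the calcium-binding Calb1 of the latter fell (−1.05 ± 0.21, adjusted p = 0.0564 over all genes). The neuron list passed when albumin replicate 1 was left out (median −0.24, adjusted p = 0.015). The neuron score of albumin replicate 2 was −0.55, against 0.12 and −0.01 in the other albumin arrays.

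The remaining lists had no member past the threshold over all genes. The 26 genes of interferon response and antigen presentation had a median of 0.57 (adjusted p = 0.0138; adjusted p = 0.564 with an estimated correlation), and 0 passed adjusted over the list alone. This rested on albumin replicate 3, whose score was 1.476 against 0.074 and 0.132, and the call ended without that array (median 0.16, adjusted p = 0.567) or sham replicate 1 (0.39, adjusted p = 0.135). The 16 cell cycle genes had a median of 0.46 (adjusted p = 0.0116; adjusted p = 0.481 with an estimated correlation). With adjustment over the list alone 1 rose, the replication factor Mcm4 (1.07 ± 0.22, adjusted p = 0.0588 over all genes). The cell cycle call ended without sham replicate 1 (median 0.305, adjusted p = 0.135), and without sham replicate 2 the median was 0.72. Medians were 3.61 for 4 neutrophil and lymphocyte genes (adjusted p = 0.068) and 0.18 for 12 complement genes (adjusted p = 0.432). They were 1.38 for 2 red cell genes (adjusted p = 0.123) and −0.55 for 6 striatum genes (adjusted p = 0.174). On adjustment over this list alone, 1 gene rose in each of the neutrophil, complement and red cell lists and 0 in the striatum list. When albumin replicate 2 was left out, the neutrophil list (median 3.40, adjusted p = 0.0451) and the red cell list (1.81, adjusted p = 0.0431) passed. The neutrophil list also passed without blockers replicate 3 (adjusted p = 0.0499). The choroid plexus list was measured by Ttr alone (−1.56 ± 1.08, adjusted p = 0.42; −3.42 without sham replicate 1, where it passed as a list at adjusted p = 0.0499). Complement C3 had 0.16 ± 0.97 (adjusted p = 0.937).

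The albumin count rested on the sham arrays: without sham replicate 1 or 2 it was 2 or 1, although all 137 genes kept their direction and an unadjusted p under 0.05. It was 112 without albumin replicate 2 (65 of the 137 remained), 79 and 56 without albumin replicates 1 and 3, and 10, 14 and 81 without blockers replicates 1, 2 and 3.

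**Figure D1:**
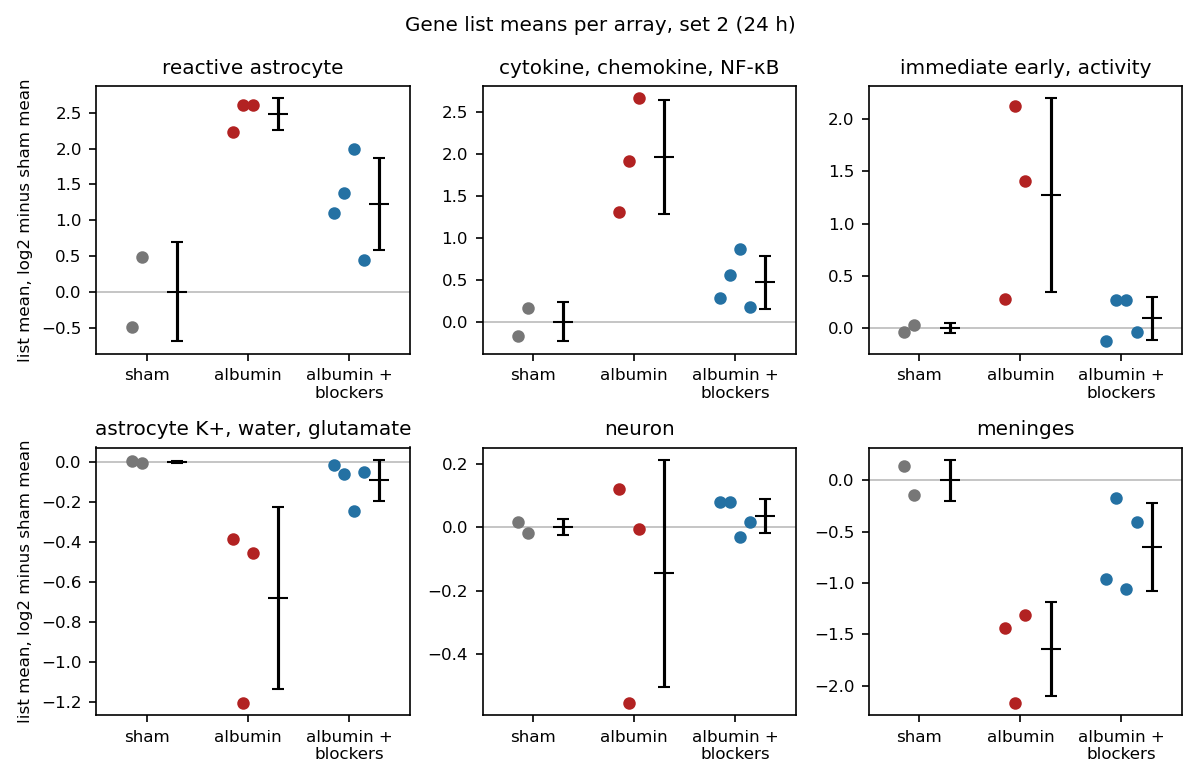
Mean log2 difference from the sham mean over the genes of 6 fixed lists, for each array of set 2 (dots), with the group mean and SD as bars, for sham (n = 2), albumin (n = 3) and albumin plus blockers (n = 4). Reactive astrocyte scores were 2.23 to 2.61 with albumin and 0.44 to 1.99 with the blockers, and meninges scores −2.17 to −1.31 and −1.06 to −0.17.

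The next comparison asked whether blocking TGF-β receptors changed the response to albumin. No sham received the blockers, so an effect of the blockers themselves is not separated from a changed response to albumin. In limma 2 genes passed, both lower with the blockers. They were Rgs16, which shortens G protein signalling (−1.37 ± 0.14; SE, n = 4 against 3; adjusted p = 0.0355), and Chdh, an enzyme of choline oxidation (−0.93 ± 0.09, adjusted p = 0.0355). Several genes that albumin had raised had lower values with the blockers without passing. They were picked as high on the same albumin arrays, and such sharing gives lower values without any change (simulated r = −0.474). Cxcl1 had −4.31 ± 0.57 (adjusted p = 0.074), Socs3 −3.65 ± 0.59 (adjusted p = 0.0804) and Klf6 −0.98 ± 0.16 (adjusted p = 0.0814). Stat3 had −1.64 ± 0.37 (adjusted p = 0.134), Vim −0.84 ± 0.18 (adjusted p = 0.118), and Eng −1.13 ± 0.19 (adjusted p = 0.0993). Of the 10334 genes, 1715 had an unadjusted p under 0.05 in limma. The calls for Rgs16 and Chdh ended when blockers replicate 1, 2 or 4 or either sham was left out. They also ended when only the arrays of the 2 groups were used, with the replicate block, and with a trend and robust prior. With a filter on a mean log2 above 5, only 1 of the 2 was tested and 0 passed. Without albumin replicates 1, 2 and 3, 28, 8 and 12 genes passed, and without blockers replicate 3, 6 passed.

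By list, 19 of 31 cytokine, chemokine and NF-kappaB genes fell adjusted over the list alone and 0 over all genes, with a median of −1.40 (camera adjusted p = 2.64e-12; adjusted p = 0.392 with an estimated correlation). It was −0.86 without albumin replicate 3 (adjusted p = 1.19e-07). Bcl3, an NF-kappaB cofactor, had −2.76 ± 0.57 (adjusted p = 0.116), Il6 −1.84 ± 0.64 (adjusted p = 0.234) and Il1b −2.72 ± 1.20 (adjusted p = 0.302). Of 23 reactive astrocyte genes, 8 fell adjusted over the list alone (median −1.27, adjusted p = 2.06e-07; adjusted p = 0.392 with an estimated correlation), while Gfap had −0.46 ± 0.29 (adjusted p = 0.423). Of 28 immediate early and activity genes, 10 fell and 1 rose adjusted over the list alone (median −0.98, adjusted p = 2.22e-07; adjusted p = 0.392 with an estimated correlation). Fosl1, an AP-1 subunit, had −4.06 ± 0.88 and Myc −2.38 ± 0.52 (both adjusted p = 0.119 over all genes). The TGF-beta list had 3 falls adjusted over the list alone and a median of −0.40 (adjusted p = 0.000301; adjusted p = 0.392 with an estimated correlation). Junb had −1.80 ± 0.39 (adjusted p = 0.123), Tgfb2 −1.16 ± 0.27 (adjusted p = 0.15) and Tgfb1 −0.79 ± 0.47 (adjusted p = 0.405). Smad7 had −0.40 ± 0.16 (adjusted p = 0.274), Smad3 0.38 ± 0.35 (adjusted p = 0.573) and Tgfbr1 0.12 ± 0.31 (adjusted p = 0.849). Without albumin replicate 2, the medians of these 4 lists were −1.15, −0.83, −0.75 and −0.16.

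In the other direction, 10 of 19 genes of astrocyte potassium, water and glutamate handling rose adjusted over the list alone (median 0.55, adjusted p = 2.06e-07; adjusted p = 0.392 with an estimated correlation). Gjb6 had 1.98 ± 0.50 (adjusted p = 0.161), Gja1 0.59 ± 0.15 (adjusted p = 0.171) and Kcnj10 0.83 ± 0.47 (adjusted p = 0.386). Slc1a3 had 0.21 ± 0.11 (adjusted p = 0.351), Aqp4 0.18 ± 0.12 (adjusted p = 0.46) and Slc1a2 0.07 ± 0.19 (adjusted p = 0.872). The median was 0.28 without albumin replicate 2. Meningeal markers moved with the blocker group too, with 5 of 12 higher adjusted over the list alone (median 1.04, adjusted p = 8.69e-05; adjusted p = 0.392 with an estimated correlation). Ptgds had 1.52 ± 0.33 (adjusted p = 0.119). P2ry12 had 2.00 ± 0.39 (adjusted p = 0.116). The channel list had a median of 0.26 (adjusted p = 0.00249; adjusted p = 0.411 with an estimated correlation) and the glutamate receptor list one of 0.21 (adjusted p = 0.00339; adjusted p = 0.422 with an estimated correlation). Neither had a member past the threshold adjusted over the list alone. Both calls ended without albumin replicate 2, with medians of 0.08 and 0.09 (adjusted p of 0.0983 and 0.103). Heat shock (−0.57, adjusted p = 0.000346), interferon (−0.41, adjusted p = 0.00278) and cell cycle genes (−0.28, adjusted p = 0.018) were lower with the blockers, and GABA (0.18, adjusted p = 0.0361), striatum (0.63, adjusted p = 0.0407) and neuron genes (0.13, adjusted p = 0.0418) higher. These 6 calls were lost with an estimated correlation, at adjusted p of 0.392 to 0.616. Without albumin replicate 2 the medians were −0.35, −0.68, −0.23, 0.10, 0.42 and −0.01, and the cell cycle, striatum and neuron calls ended (adjusted p of 0.0505, 0.0983 and 0.775). The interferon call ended without albumin replicate 3 (median −0.10, adjusted p = 0.834), as did the GABA call (adjusted p = 0.0978). Without albumin replicate 1 the cell cycle and striatum calls ended (adjusted p of 0.112 and 0.078), and oligodendrocyte genes passed (median 0.305, adjusted p = 0.00265). That omission also gave medians of 0.45 for the channel, 0.345 for the glutamate receptor, 0.25 for the neuron and −0.705 for the interferon list. Leaving out single blocker arrays ended the neuron call (adjusted p of 0.0709 and 0.137 without replicates 1 and 2), the striatum call (0.137 without replicate 2) and the cell cycle call (0.0693 without replicate 4). The oligodendrocyte (0.21, adjusted p = 0.00883) and neutrophil lists (−2.55, adjusted p = 0.031) passed without blockers replicate 3.

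With the blockers present, no gene differed from sham at the threshold in limma, and 444 had an unadjusted p under 0.05 (n = 4 against 2). The smallest p belonged to the zinc exporter Slc30a1 (1.30 ± 0.15) and Med8 of the Mediator complex (0.98 ± 0.12) on the higher side (both adjusted p = 0.118). On the lower side it belonged to the integrin Itgb4 (−0.77 ± 0.10, adjusted p = 0.118). Pik3r1 had 4.75 ± 0.70 (adjusted p = 0.22), and Ccl2 4.93 ± 0.99 (adjusted p = 0.579). Stat3 had 1.01 ± 0.42, Gfap 0.82 ± 0.33, Il6 −0.06 ± 0.72, Il1b 0.06 ± 1.36 and Tgfb1 0.02 ± 0.53 (each adjusted p = 1). All 23 reactive astrocyte genes were above sham (median 0.95, adjusted p = 1.3e-11; adjusted p = 0.592 with an estimated correlation), 0 of them past the threshold adjusted over the list alone. The cytokine list had a median of 0.18 (adjusted p = 0.00435; adjusted p = 0.958 with an estimated correlation). The meninges list had one of −0.57 (adjusted p = 6.19e-05; adjusted p = 0.643 with an estimated correlation). The heat shock list had 0.26 (adjusted p = 0.00513), the oligodendrocyte list −0.12 (adjusted p = 0.0322) and the red cell list 1.496 (adjusted p = 0.00513), with both of its genes higher adjusted over the list alone. These 3 calls were lost with an estimated correlation, at adjusted p of 0.592 to 0.987. The oligodendrocyte call also ended without albumin replicate 2 (adjusted p = 0.0599), while the astrocyte potassium list passed (median −0.10, adjusted p = 0.0259 against 0.0771). It ended too without blockers replicate 1 (−0.11, adjusted p = 0.0812) or 3 (−0.02, adjusted p = 0.571) or sham replicate 1 (−0.08, adjusted p = 0.232), and its median was −0.25 without blockers replicate 4 and −0.19 without sham replicate 2. The cytokine, heat shock and red cell calls ended without sham replicate 1 (adjusted p of 0.0568, 0.0924 and 0.0551), and Ttr for choroid plexus then passed (−3.00, adjusted p = 0.00735). The cytokine median was 0.33 without blockers replicate 1. Without sham replicate 2 the microglia (0.62, adjusted p = 5.7e-05) and cell cycle lists (0.35, adjusted p = 0.000219) passed, the latter also without blockers replicate 4 (0.235, adjusted p = 0.0308). The TGF-beta list had 0.12 (adjusted p = 0.368), and the immediate early list a median of 0.03 where the test pointed lower (adjusted p = 0.831).

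Genes picked in the animals of set 1 were then followed in set 2, so that no array was shared between choice and test. The 466 genes at least 2-fold higher on the set 1 albumin array at 24 h than on its sham averaged 1.42 ± 0.31 above sham with albumin (SD, n = 3). They averaged 0.54 ± 0.32 with albumin plus blockers (SD, n = 4), and the sham arrays lay at −0.23 and 0.23. With albumin 447 of them were higher than sham (fry p of 0.00157), and with the blockers 419 were lower than with albumin alone (mean −0.88, fry p of 0.00725). The 249 genes lower in set 1 averaged −0.90 ± 0.47 with albumin (217 lower, fry p of 0.0106) and −0.25 ± 0.21 with the blockers. With the blockers 212 were higher than with albumin alone (mean 0.65, fry p of 0.0212). With an estimated correlation, camera p of 0.0217 and 0.0347 was found for the higher genes and camera p of 0.0573 and 0.0771 for the lower ones, the last 2 above 0.05. For the higher genes against albumin alone it was above 0.05 without albumin replicate 2 (camera p of 0.0729) or 3 (0.0864) or blockers replicate 1 (0.0513), and against sham without albumin replicate 3 (0.0538). For the lower genes of albumin against sham it was 0.0375 without albumin replicate 2, with a mean of −0.64. The mean difference from sham left with the blockers was 37.8% of that with albumin for the higher genes and 27.8% for the lower ones. These shares were 26.2 to 46.4% and 20.7 to 39.5% when 1 array was left out. As no sham received the blockers, the shares may also hold an effect of the blockers themselves. Against sham, the blocker group had fry p of 0.081 and 0.354. For the higher genes this rested on single arrays, with a mean of 0.66 and fry p of 0.038 without blockers replicate 4 and a mean of 0.31 and fry p of 0.389 without sham replicate 1. On the array means, the exact two-sided permutation test of blockers against albumin gave p = 0.0571 for both lists, the smallest that 35 splits allow. For albumin against sham the exact permutation test gave p = 0.2 for both, the smallest that 10 splits allow, and for blockers against sham p = 0.267 and 0.4, where 15 splits allow 0.133. The call on the lower genes ended without blockers replicate 1 (mean 0.64, fry p of 0.0504).

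**Figure D2:**
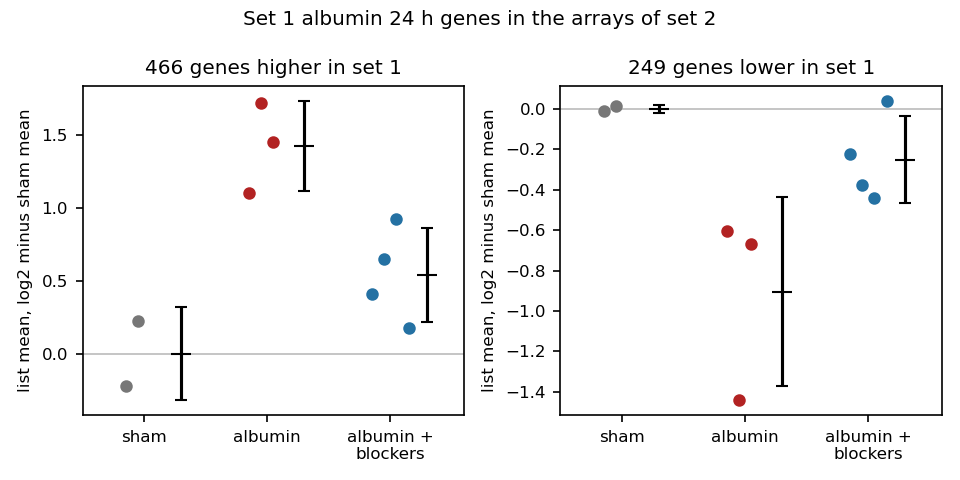
Mean log2 difference from the sham mean in each array of set 2 (dots) of the 466 genes higher and the 249 genes lower in the set 1 albumin array at 24 h, with group means and SD as bars. The higher genes lay at 1.10 to 1.72 with albumin and at 0.18 to 0.92 with albumin plus blockers.

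In set 1, each agent was compared with the lone sham over its 3 times. With DOC, 47 of 10023 genes passed, 32 higher and 15 lower. Ccl2 rose by 6.79 ± 0.62 (SE, n = 3 against 1; adjusted p = 0.0295). The secreted phosphoprotein Spp1 rose by 6.49 ± 0.92, the lipopolysaccharide co-receptor Cd14 by 5.07 ± 0.57, the haem-degrading enzyme Hmox1 by 4.98 ± 0.70 and Lgals3 by 3.81 ± 0.40 (each adjusted p = 0.0458). Calca, which encodes calcitonin and CGRP, rose by 3.19 ± 0.29 (adjusted p = 0.0295). The sham signals of Ccl2 (2.83), Spp1 (2.97), Cd14 (2.17), Hmox1 (3.58), Cybb (2.32), Tlr2 (2.31) and Col6a3 (2.50) lay below the log2 of 4 used in the filter. The sizes of their rises therefore rest on background. The largest fall was in the pseudogene Brcc3-ps7 (−5.93 ± 0.29, adjusted p = 0.00171). Falls followed in Lgals9 (−2.53 ± 0.33), Ddc (−2.50 ± 0.29), G0s2, an inhibitor of lipolysis (−2.38 ± 0.32), and Psd (−2.12 ± 0.25), each at adjusted p = 0.0458. Of 22 reactive astrocyte genes 4 rose, among them Vim (2.01 ± 0.26) and Stat3 (1.66 ± 0.19). When adjustment was over the list alone, 17 rose (median 2.07, camera adjusted p = 8.09e-16; adjusted p = 0.222 with an estimated correlation). Of 22 microglia and macrophage genes 2 rose, Cd14 and the NADPH oxidase gene Cybb (2.58 ± 0.35, adjusted p = 0.0458). Adjusted over the list alone, 10 rose (median 1.16, adjusted p = 6.25e-08; adjusted p = 0.222 with an estimated correlation). Of 30 cytokine genes 2 rose, Ccl2 and Tlr2 (1.66 ± 0.20), and 9 rose and 1 fell adjusted over the list alone (median 1.13, adjusted p = 6.35e-08; adjusted p = 0.172 with an estimated correlation). Of 36 matrix genes 3 rose, Spp1, Col6a3 (1.82 ± 0.23) and Nid1 (1.47 ± 0.20), and 11 rose adjusted over the list alone (median 0.63, adjusted p = 1.4e-06; adjusted p = 0.23 with an estimated correlation). The 33 glutamate receptor and synapse genes had 2 falls adjusted over the list alone and a median of −0.33 (adjusted p = 0.00171; adjusted p = 0.182 with an estimated correlation). The TGF-beta list had a median of 0.28 (adjusted p = 0.0521), with Tgfb1 at 0.72 ± 0.45 (adjusted p = 0.441), and Gfap had 0.42 ± 0.41 (adjusted p = 0.623). Other lists past the threshold were cell cycle (median 1.20, adjusted p = 2.4e-10), heat shock (0.59, adjusted p = 2.17e-07), complement (0.30, adjusted p = 0.0427) and red cell (1.66, adjusted p = 0.00541). Lower were the astrocyte potassium list (−0.36, adjusted p = 0.00541) and the neuron list (−0.23, adjusted p = 0.00595). All 6 were lost with an estimated correlation, at adjusted p of 0.23 to 0.327.

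Albumin in set 1 gave 37 genes, 34 higher and 3 lower. Ccl2 rose by 6.89 ± 0.62 (n = 3 against 1; adjusted p = 0.0178), Spp1 by 6.73 ± 0.92 (adjusted p = 0.0486), Cd14 by 6.0 ± 0.57 (adjusted p = 0.0232), and the protease inhibitor Slpi by 5.44 ± 0.57 (adjusted p = 0.0268). Fgl2, a membrane protein of activated macrophages, rose by 5.03 ± 0.40 (adjusted p = 0.0178) and Lgals3 by 4.49 ± 0.40 (adjusted p = 0.0178). The sham signals of Ccl2, Spp1 and Cd14 as above, and of Slpi (2.72) and Fgl2 (3.72), lay below the log2 of 4 of the filter, so that the sizes of these rises rest on background. The 3 falls were in Cyp4f4, a fatty acid hydroxylase (−2.33 ± 0.26, adjusted p = 0.0282), Ddc (−2.21 ± 0.29, adjusted p = 0.0385) and Trerf1 (−1.49 ± 0.20, adjusted p = 0.0487). Of 22 reactive astrocyte genes 6 rose, among them Vim (2.48 ± 0.26) and Stat3 (1.83 ± 0.19). With adjustment over the list alone, 19 rose (median 2.73, adjusted p = 1.14e-26; adjusted p = 0.0912 with an estimated correlation). Of 22 microglia and macrophage genes 4 rose, 15 adjusted over the list alone, with the Fc receptor Fcgr2b at 2.96 ± 0.38 (median 1.37, adjusted p = 4.18e-12; adjusted p = 0.0912 with an estimated correlation). Matrix genes had 3 rises of 36, and 15 adjusted over the list alone (median 0.82, adjusted p = 4.53e-14; adjusted p = 0.0912 with an estimated correlation). Cytokine genes had 2 rises of 30, and 11 rises and 1 fall adjusted over the list alone (median 1.48, adjusted p = 6.33e-13; adjusted p = 0.0652 with an estimated correlation). On the mean of the 3 times, all 11 meningeal markers were above the sham (median 0.61, adjusted p = 9.84e-05, or adjusted p = 0.162 with an estimated correlation). Of them, 1 passed the threshold adjusted over the list alone and 0 over all genes. On the 24 h array alone, 6 of the 11 were below the sham (median −0.061). Tgfb1 had 0.97 ± 0.45 (adjusted p = 0.462), Gfap 1.21 ± 0.41 (adjusted p = 0.305), Il6 1.91 ± 1.03 (adjusted p = 0.548) and Il1b 1.54 ± 1.09 (adjusted p = 0.671). Other lists past the threshold were cell cycle (median 1.03, adjusted p = 1.92e-12), heat shock (0.52, adjusted p = 2.93e-08), interferon (0.75, adjusted p = 5.45e-05) and red cell (1.98, adjusted p = 0.000427). So were complement (0.45, adjusted p = 0.00164), neutrophil (3.21, adjusted p = 0.00357), glutamate receptor (−0.27, adjusted p = 0.00206) and astrocyte potassium genes (−0.23, adjusted p = 0.044). All 8 were lost with an estimated correlation, at adjusted p of 0.0912 to 0.379.

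With TGF-β1, no gene passed in limma, and 751 had an unadjusted p under 0.05. Nearest the threshold on the higher side was Calca (3.38 ± 0.29; n = 3 against 1; adjusted p = 0.0801). Next were Lgals3 3.98 ± 0.40, Fgl2 3.79 ± 0.40, Vim 2.36 ± 0.26, Ccl2 5.46 ± 0.62 and Cd14 4.70 ± 0.57 (each adjusted p = 0.0955), with Fgl2, Ccl2 and Cd14 below a log2 of 4 in the sham, as above. On the lower side, Ddc had −2.14 ± 0.29 and Cyp4f4 −1.85 ± 0.26 (both adjusted p = 0.105). On adjustment over this list alone, 18 of 22 reactive astrocyte genes rose (median 2.29, adjusted p = 8.51e-24), as did 13 of 22 microglia and macrophage genes (median 1.21, adjusted p = 1.12e-13). So did 11 of 36 matrix genes (median 0.69, adjusted p = 1.66e-13) and 5 of 30 cytokine genes (median 0.78, adjusted p = 1.73e-06). Each of these 4 calls was lost, at adjusted p = 0.0752 with an estimated correlation. Immediate early genes had a median of −0.65 (adjusted p = 0.000246; adjusted p = 0.281 with an estimated correlation), with the orphan nuclear receptor Nr4a1 at −2.01 ± 0.44 (adjusted p = 0.241). The TGF-beta list had 0.27 (adjusted p = 0.073), with Tgfb1 at 0.94 ± 0.45 (adjusted p = 0.748) and Smad7 at 0.27. All 11 meningeal markers were above the sham (median 0.71, adjusted p = 7.56e-06), as were both red cell genes (1.67, adjusted p = 0.000252). Other lists on the higher side were cell cycle (0.87, adjusted p = 2.84e-11), complement (0.54, adjusted p = 0.000246), heat shock (0.41, adjusted p = 0.00118) and oligodendrocyte (0.28, adjusted p = 0.00245). Interferon (0.40, adjusted p = 0.0155) and neutrophil genes (1.96, adjusted p = 0.0308) were there too. On the lower side were glutamate receptor (−0.22, adjusted p = 0.000138), channel (−0.15, adjusted p = 0.0035), neuron (−0.09, adjusted p = 0.0114) and GABA genes (−0.07, adjusted p = 0.0156), and Ttr for choroid plexus (−1.79, adjusted p = 0.0402 as a list). All of these calls were lost with an estimated correlation, at adjusted p of 0.0752 to 0.545.

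The counts against the lone sham moved with the filter and with single arrays. With no filter DOC gave 18 higher and 57 lower genes and albumin 12 higher and 30 lower, so that lower genes were then the majority, and 21 of the 47 and 10 of the 37 genes remained. In a model of all 19 arrays DOC gave 136 higher and 220 lower. Without the DOC array at 48 h, DOC gave 202 genes, albumin 117 and TGF-β1 2. DOC gave 1 to 6 genes without any other DOC array, the 8 h albumin array or any TGF-β1 array, and 19 and 15 without the 24 h and 48 h albumin arrays. Albumin gave 2 to 12 without the 8 h albumin array or any TGF-β1 array and 22 without the 24 h albumin array, and TGF-β1 gave 3 and 5 without the DOC arrays at 7 and 24 h. All 47 and 37 calls kept their direction, and because the sham was single, its own deviation enters all 3 comparisons.

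Single arrays were set against the sham, where Ccl2 (2.83), Lcn2 (2.11) and, nearly, Timp1 (4.15) were at background, so that these sizes are uncertain. Ccl2 was 5.76, 7.88 and 6.73 above sham at 7, 24 and 48 h with DOC, 6.89, 7.29 and 6.48 at 8, 24 and 48 h with albumin, and 5.63, 5.19 and 5.57 with TGF-β1. Lcn2, an iron-binding protein of reactive astrocytes, went from 4.47 to 6.69 with DOC, from 5.23 to 7.15 and 4.75 with albumin, and from 3.29 to 6.60 with TGF-β1. Timp1, an inhibitor of matrix proteases, was 6.52, 5.87 and 7.21 above sham with albumin and 4.61, 6.19 and 7.00 with TGF-β1. On the lower side, Nr4a1 was −2.00, −2.69 and −3.55 with DOC and −2.12, −2.91 and −2.12 with albumin, and the neuronal activity gene Arc was −1.60, −1.98 and −1.96 with TGF-β1. Genes at least 2-fold higher than sham at all 3 times numbered 106 with DOC, 166 with albumin and 99 with TGF-β1, and 88, 42 and 27 were lower. Of those higher, 67 were shared by DOC and albumin, 75 by albumin and TGF-β1, 49 by DOC and TGF-β1 and 45 by all 3. Simulated unchanged groups around 1 shared sham gave 4.45 shared genes for a pair on average, at most 11, and 2.56 for 3 groups. Of those lower, 19 were shared by DOC and albumin, 13 by albumin and TGF-β1, 12 by DOC and TGF-β1 and 7 by all 3. On that side the simulation gave at most 10 for a pair and 8 for 3 groups, so the 7 lay within its range. Part of the excess may come from the shared sham.

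**Figure D3:**
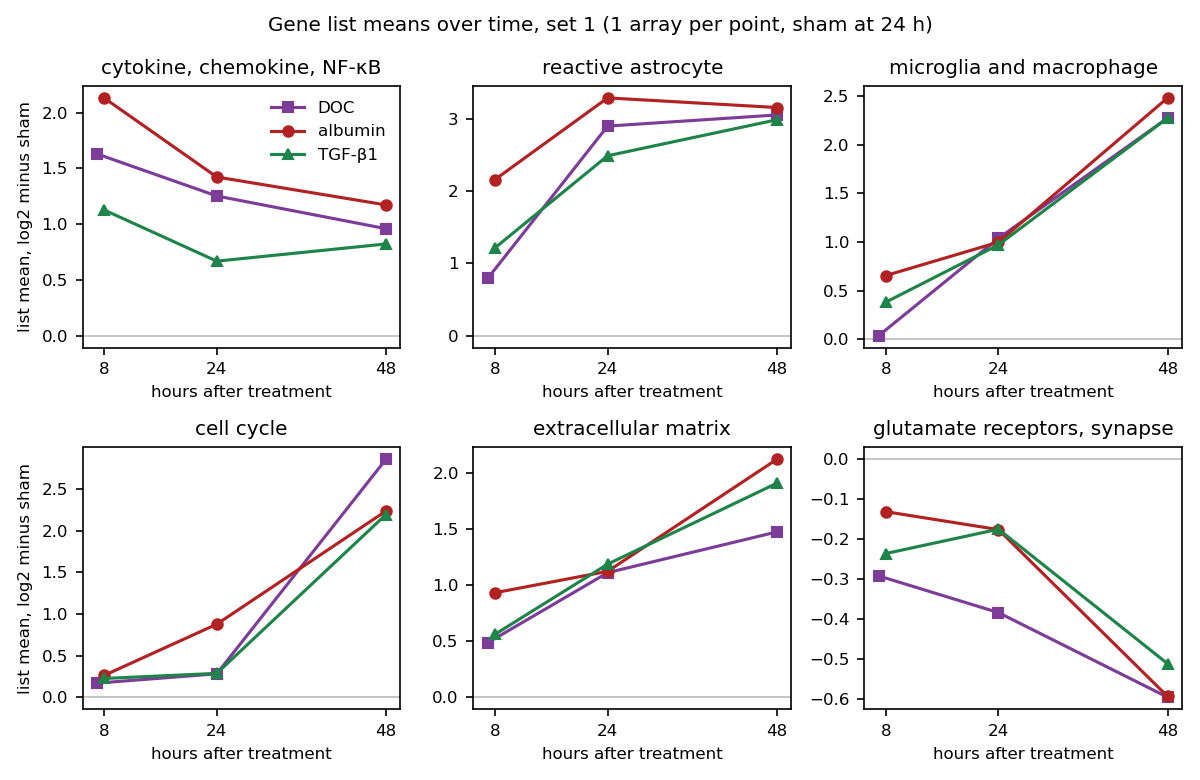
Mean log2 difference from the set 1 sham over the genes of 6 fixed lists at 7 or 8, 24 and 48 h, with 1 array per point and 1 line per agent. Cell cycle scores were 0.17 to 0.26 at 7 or 8 h and 2.19 to 2.86 at 48 h, and cytokine scores 1.13 to 2.13 and 0.82 to 1.17.

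The times were compared across the 3 agents, without the sham, so that effects of the agents were not separated from the time since surgery. From the early time to 24 h, 80 genes passed, 50 higher and 30 lower. The small heat shock protein Hspb1 rose by 4.99 ± 0.53 (SE, n = 3 against 3; adjusted p = 0.024) and the astrocyte protease inhibitor Serpina3n by 3.42 ± 0.42 (adjusted p = 0.0311). Lgals3 rose by 3.00 ± 0.28 (adjusted p = 0.0155) and Calca by 2.84 ± 0.21 (adjusted p = 0.0126). Falls were found in Depp1 (−3.96 ± 0.40, adjusted p = 0.0212) and the prostaglandin E synthase Ptges (−3.35 ± 0.44, adjusted p = 0.0357). Pdk4, which restrains glucose oxidation (−2.50 ± 0.35, adjusted p = 0.0387), also fell, as did Fkbp5, a glucocorticoid-induced chaperone (−2.01 ± 0.17, adjusted p = 0.0155). Of 22 reactive astrocyte genes 8 rose, 11 adjusted over the list alone (median 1.20, camera adjusted p = 5.96e-12; adjusted p = 0.351 with an estimated correlation). Of 22 microglia and macrophage genes 4 rose, among them Tyrobp (1.13 ± 0.15, adjusted p = 0.0387). When adjustment was over the list alone, 10 rose (median 0.57, adjusted p = 7.39e-05; adjusted p = 0.351 with an estimated correlation). Other lists past the threshold were complement (0.72, adjusted p = 0.00245), matrix (0.31, adjusted p = 0.0041) and TGF-beta genes (0.22, adjusted p = 0.0382). Lower were channel (−0.19, adjusted p = 0.00245), astrocyte potassium (−0.14, adjusted p = 0.00291), oligodendrocyte (−0.13, adjusted p = 0.00406), striatum (−0.68, adjusted p = 0.0162) and red cell genes (−0.65, adjusted p = 0.0414). All 8 were lost with an estimated correlation, at adjusted p of 0.313 to 0.481. The count was 1 to 8 without any 1 early or 24 h array, 4 without the TGF-β1 array at 48 h and 126 without the DOC array at 48 h. It was 0 with no filter, and all 80 genes kept their direction in each case.

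From the early time to 48 h, 510 genes passed, 392 higher and 118 lower. Of 26 cell cycle genes 18 rose, among them the mitotic kinase Cdk1 (4.09 ± 0.46, adjusted p = 0.00574) and Ect2 (3.36 ± 0.17, adjusted p = 0.000652). Adjusted over the list alone, 25 rose (median 2.55, adjusted p = 9.65e-23; adjusted p = 0.14 with an estimated correlation). Of 22 microglia and macrophage genes 17 rose, among them the lysosomal Cd68 (3.57 ± 0.23, adjusted p = 0.000968) and Cybb (4.36 ± 0.25, adjusted p = 0.000909). With adjustment over the list alone, 21 rose. The list median was 1.86 (adjusted p = 1.12e-19), and the call held at adjusted p = 0.0459 with an estimated correlation. Of 11 complement genes 5 rose, 9 adjusted over the list alone, with C1qc at 2.24 ± 0.19 (adjusted p = 0.00225). This call held as well (median 0.82, adjusted p = 6.27e-08; adjusted p = 0.0459 with an estimated correlation). Matrix genes had 14 rises of 36, and 20 rises and 1 fall adjusted over the list alone (median 0.99, adjusted p = 6.93e-11; adjusted p = 0.14 with an estimated correlation). Fbln2, a basement membrane protein, rose by 2.91 ± 0.15 (adjusted p = 0.000652). Reactive astrocyte genes had 12 rises of 22, and 15 rises and 1 fall adjusted over the list alone (median 1.86, adjusted p = 5.77e-10; adjusted p = 0.206 with an estimated correlation).

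Genes of neuronal excitability went the other way at 48 h. Of 41 channel genes 2 fell, Kcnq3 of the M current (−0.92 ± 0.14, adjusted p = 0.015) and the sodium channel subunit Scn3b (−0.64 ± 0.13, adjusted p = 0.0446). On adjustment over this list alone, 4 fell. Of the list, 39 had lower values (median −0.39, adjusted p = 2.72e-08), a call that held at adjusted p = 0.0459 with an estimated correlation. Of 33 glutamate receptor and synapse genes 2 fell and 1 rose, or 7 and 1 adjusted over the list alone. The vesicular transporter Slc17a6 fell (−2.12 ± 0.44, adjusted p = 0.0431) and the NMDA receptor subunit Grin2c rose (1.12 ± 0.19, adjusted p = 0.0215). The list median was −0.32 (adjusted p = 3.44e-05), and this call held too, at adjusted p = 0.0459 with an estimated correlation. Among 30 cytokine genes 6 fell, including Il6 (−3.78 ± 0.73, adjusted p = 0.0356), Cxcl1 (−3.09 ± 0.66, adjusted p = 0.0472) and Tnf (−2.56 ± 0.52, adjusted p = 0.041). When adjustment was over the list alone, 4 rose and 7 fell (median −0.16, adjusted p = 0.0399; adjusted p = 0.236 with an estimated correlation). In the TGF-beta list 2 of 23 genes rose, Tgfbr1 (1.69 ± 0.19, adjusted p = 0.0058) and the BMP target Id3 (1.16 ± 0.23, adjusted p = 0.0377; list median 0.28, adjusted p = 0.0997). Meningeal markers moved with the 48 h arrays, with 4 of 11 higher, among them Col1a1 (1.49 ± 0.27, adjusted p = 0.0296). Adjusted over the list alone, 8 rose and 1 fell (median 1.42, adjusted p = 0.000663; adjusted p = 0.206 with an estimated correlation). Both red cell genes, Alas2 and Hbb, fell (median −1.38, adjusted p = 0.00354), and of 22 endothelium and pericyte genes 8 rose and 1 fell (median 0.80, adjusted p = 0.000169). Lower lists were immediate early (−0.75, adjusted p = 9.19e-06), heat shock (−0.25, adjusted p = 0.0314), striatum (−0.61, adjusted p = 0.0314) and oligodendrocyte (−0.12, adjusted p = 0.0435), and interferon genes were higher (0.48, adjusted p = 0.0236). These 7 calls were lost with an estimated correlation, at adjusted p of 0.206 to 0.53. The count was 167 to 338 without any 1 of the 3 early arrays, the DOC or TGF-β1 array at 48 h or the TGF-β1 array at 24 h, and 286 with no filter.

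From 24 h to 48 h, 141 genes passed, 130 higher and 11 lower. Cell cycle genes made up 14 of the rises, with 21 of 26 higher adjusted over the list alone (median 2.24, adjusted p = 1.05e-23; adjusted p = 0.132 with an estimated correlation). Pttg1, a regulator of chromatid separation, rose by 3.78 ± 0.18 (adjusted p = 0.00135). Of 22 microglia and macrophage genes 7 rose, among them Cd68 (3.43 ± 0.23, adjusted p = 0.00256). With adjustment over the list alone, 18 rose (median 1.17, adjusted p = 5.64e-16; adjusted p = 0.128 with an estimated correlation). The fibrillar collagen Col1a2 rose by 3.43 ± 0.32 (adjusted p = 0.00623) and complement C3 by 1.53 ± 0.17 (adjusted p = 0.0106). Fosl1, an AP-1 subunit, fell by 1.92 ± 0.30 (adjusted p = 0.0375). Other lists on the higher side were meninges (1.11) and matrix (0.65, both adjusted p = 7.73e-07), complement (0.39, adjusted p = 0.000339), endothelium (0.31, adjusted p = 0.00449) and interferon genes (0.34, adjusted p = 0.00839). On the lower side were immediate early (−0.68, adjusted p = 3.75e-05), glutamate receptor (−0.30, adjusted p = 7.29e-05), channel (−0.22, adjusted p = 0.00264) and heat shock genes (−0.34, adjusted p = 0.00839). All 9 were lost with an estimated correlation, at adjusted p of 0.128 to 0.693. The count was 35 to 93 without any 1 array except the DOC array at 48 h, which gave 103, and it was 57 with no filter and 50 with a filter on a mean log2 above 5.

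Whether the agents differed from each other was tested on the treated arrays. Between albumin and DOC 1 gene passed, Brcc3-ps7, higher with albumin by 5.95 ± 0.21 (SE, n = 3 against 3; adjusted p = 0.000152). Between TGF-β1 and DOC 3 passed. Brcc3-ps7 (4.82 ± 0.21, adjusted p = 0.000655) and Psd (2.04 ± 0.18, adjusted p = 0.0288) were higher with TGF-β1. Ubn1, a histone chaperone subunit, was lower (−1.41 ± 0.11, adjusted p = 0.0197). In set 2 the signal of Brcc3-ps7 was 2.14 to 2.24 on 3 of the 7 arrays with albumin and 8.48 to 9.72 on the other 4 and the shams, so its low values were not confined to DOC. The calls for Psd and Ubn1 ended without the 7 h or 24 h DOC array, the 8 h or 48 h albumin array or any 1 TGF-β1 array, and without the DOC array at 48 h or the albumin array at 24 h the count was 179 or 6. Between TGF-β1 and albumin none passed in limma, and 878 genes had an unadjusted p under 0.05, with Colgalt2 at −1.38 ± 0.18 and Stat3 at −0.59 ± 0.14 (both adjusted p = 0.493). By list, all 22 reactive astrocyte genes were lower with TGF-β1 than with albumin (median −0.59, adjusted p = 2.02e-08; adjusted p = 0.578 with an estimated correlation). All 22 were higher with albumin than with DOC (median 0.55, adjusted p = 3.21e-06; adjusted p = 0.455 with an estimated correlation). Cytokine genes were lower with TGF-β1 than with albumin in 26 of 30 cases (median −0.49, adjusted p = 3.5e-08; adjusted p = 0.151 with an estimated correlation). Interferon and antigen presentation genes were higher with albumin than with DOC in 24 of 25 cases (median 0.70, adjusted p = 3.21e-06; adjusted p = 0.455 with an estimated correlation). Irf7, a regulator of interferon genes, had 2.17 ± 0.74 (adjusted p = 0.645). The 18 astrocyte potassium, water and glutamate genes were all higher with TGF-β1 than with DOC (median 0.35, adjusted p = 0.00305; adjusted p = 0.73 with an estimated correlation). Meningeal genes were higher with albumin than with DOC (0.65, adjusted p = 4.06e-06), as were matrix (0.30, adjusted p = 0.000374), neuron (0.15, adjusted p = 0.0158), striatum (0.59, adjusted p = 0.0169) and astrocyte potassium genes (0.20, adjusted p = 0.0373). With TGF-β1, heat shock (−0.37, adjusted p = 0.000287) and cytokine genes (−0.38, adjusted p = 0.0129) were lower than with DOC, and meningeal (0.78, adjusted p = 0.00312) and striatum genes (0.85, adjusted p = 0.0248) higher. Oligodendrocyte (0.32), immediate early (−0.24) and cell cycle genes (−0.17) followed, each at adjusted p = 0.0265. Against albumin, TGF-β1 had lower heat shock (−0.35, adjusted p = 4.62e-06), immediate early (−0.36, adjusted p = 0.00036), interferon (−0.33, adjusted p = 0.00368), cell cycle (−0.25, adjusted p = 0.015), matrix (−0.12, adjusted p = 0.0341) and neutrophil genes (−1.25, adjusted p = 0.041). It had higher oligodendrocyte (0.30, adjusted p = 0.00036), astrocyte potassium (0.18, adjusted p = 0.0225) and endothelium genes (0.22, adjusted p = 0.0495). All of these were lost with an estimated correlation, at adjusted p of 0.455 to 0.869. No member of these lists passed over all genes.

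Across 10023 genes, which are not independent replicates, the mean differences from sham correlated at r = 0.874 between DOC and albumin (rho 0.838), 0.849 between albumin and TGF-β1 (rho 0.702) and 0.758 between DOC and TGF-β1 (rho 0.62). Unchanged groups simulated around the shared sham gave r = 0.749 to 0.75. The covariances were 0.285, 0.212 and 0.198, against simulated ones of 0.0689 to 0.0695, and part of that excess may come from the shared sham. Between the sets, where no array was shared, the 24 h differences of set 1 were set against albumin minus sham of set 2 across 9846 genes. They correlated at r = 0.727 for albumin (rho 0.593), 0.652 for DOC (rho 0.555) and 0.526 for TGF-β1 (rho 0.412). Of 92 genes higher in set 2 albumin and 33 higher in set 1 albumin, 9 were shared, against 0.308 for independent lists. Within set 2, the albumin minus sham and blockers minus albumin differences correlated at r = −0.899, but they share the albumin arrays, and simulated unchanged groups gave r = −0.474 (covariance −0.251 against −0.0307).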

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

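The tests of RNA degradation and of a neuron share in albumin replicate 2, and of whether albumin lowers the meningeal genes, were chosen only after the result was seen.

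On the striatum list, the score of albumin plus blockers replicate 2 was 0.706, far from the other 3 arrays of its group (gap ratio 0.919, past the 95% critical value for 4 samples). It was the 1 array found in 42 groups tested, and chance alone gives about 1 in 20 groups. With all probe sets tested, 11 of 4604 probe sets without a gene name passed in set 2 albumin against sham (8 higher, 3 lower), and 1 passed in blockers against sham.

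The meninges score with albumin lay above the sham on the 3 arrays of set 1 (0.666, 0.133 and 1.915 at 8, 24 and 48 h, mean 0.905) and below it on the 3 of set 2 at 24 h (mean −1.64). The difference of −2.545 was not tested, and at the matched time of 24 h the set 1 score was only 0.133. Over the 3 times together, the list test of set 1 had these genes higher with albumin than in the sham. That direction is opposite to a lowering by albumin, but the call was lost with an estimated correlation and the sham was taken at 24 h alone. Neither explanation weighed for the lower values in set 2 was excluded. A different share of meningeal tissue between samples remains a candidate explanation. Within groups the listed genes varied together across the 9 arrays (mean pairwise correlation of residuals 0.411). Random lists of like expression had a median of −0.013 and a 95th percentile of 0.116. Markers of the same tissue can also vary together when regulated in common, so this test does not single out a tissue share. Lowering by albumin stays open: in set 1 at 24 h the median of 11 of these genes was −0.061 against the single sham, with 6 of 11 below 0. The 95% interval of −0.285 to 0.35 came from resampling these genes, so it holds no spread between animals. A difference in processing between the sets was not tested.

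Albumin replicate 2 of set 2 stood apart, with a median correlation of 0.981 with the other arrays of its set against 0.992 to 0.995 for the rest. RNA degradation is argued against by its actin 3′ minus 5′ difference of 1.838, the lowest of the set (others 1.93 to 2.215). The 95% intervals that follow come from resampling the genes of each list, so they hold no spread between animals. A lower share of neurons would raise the markers of other cell types alike. The astrocyte potassium, water and glutamate list instead lay at a median of −0.573 from the other 2 albumin arrays (95% interval −0.846 to −0.421). Albumin lowered that list against sham without this replicate too (median −0.39), so its low value cannot decide the question. The oligodendrocyte list was low as well (−0.477, interval −0.596 to −0.195), and the microglia and endothelium intervals included 0. The neuron list lay at −0.487 (interval −0.635 to −0.285), so that a lower share of neurons stays open. A stronger response to albumin in that animal may account for part of the distance, as a hypothesis: across genes, its deviation correlated with the set 1 albumin difference at 24 h at r = 0.31, just past the bound of 0.3 set beforehand. The same measure was −0.353 and −0.113 for the other 2 arrays, but the 3 deviations sum to 0, so that the size of r does not single out replicate 2, and the intervals of its cytokine and reactive astrocyte lists included 0.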

How the results depend on the processing

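The list tests of set 2 with 1 array left out were chosen only after the result was seen; all other alternatives were chosen before the data were examined. Counts are of genes past the threshold. For set 2 albumin against sham (137), blockers against albumin (2) and blockers against sham (0), with all probe sets tested the counts were 61, 5 and 1, with the replicate block 53, 0 and 1, and with only the 2 groups 4, 0 and 2. With no expression filter the first 2 were 27 and 1, with an added 2-fold minimum 87 and 1, at adjusted p under 0.1 631 and 37, and in a model of all 19 arrays 798 and 31. A median shift gave 89 for albumin, and a filter at mean log2 above 5 and a trend and robust prior gave 0 for the blockers. For set 1 DOC (47), albumin (37) and TGF-β1 (0) against sham, adjusted p under 0.1 gave 228, 128 and 9, and all 19 arrays 356, 171 and 15. With the set 2 shams added, 3278, 1416 and 17 passed, most of them lower (3006, 1260 and 12), while the median of all genes moved to −0.614, −0.601 and −0.567, so that these counts carry the difference between the sets. DOC and albumin gave 1 and 13 with the mean of probe sets and 3 and 2 with no time term. DOC gave 75 with no filter (18 higher, 57 lower) and set 1 albumin 42 (12 higher, 30 lower), so that the majority turned, as it did for DOC with 19 arrays (136 higher, 220 lower). DOC also gave 5 after another quantile normalization and 12 with all probe sets. Albumin gave 61 with a median shift and 61 with a trend and robust prior, and TGF-β1 gave 6 with no filter, 1 with mean log2 above 5 and 7 with the trend and robust prior. For 24 against 7/8 h (80), 48 against 7/8 h (510) and 48 against 24 h (141), no filter gave 0, 286 and 57 and adjusted p under 0.1 186, 931 and 284. The first gave 29 with all probe sets and 129 with the trend and robust prior, the second 338 with the 2-fold minimum, and the third 50 with mean log2 above 5. TGF-β1 against DOC (3) gave 1 with all probe sets and 232 at adjusted p under 0.1. The 2-fold minimum and the adjusted p of 0.1 act by construction; for the other moved counts the cause was not tested. Albumin against DOC gave 1 and TGF-β1 against albumin 0 under every alternative run. Wherever tested again, all genes that passed kept their direction, except that with the set 2 shams added 36 of the 37 of set 1 albumin did.

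With 1 array left out, the ranges were 1 to 190 for set 2 albumin, 0 to 28 for blockers against albumin, 0 to 1 for blockers against sham, 1 to 202 for DOC, 2 to 117 for set 1 albumin, 0 to 5 for TGF-β1, 1 to 126 for 24 against 7/8 h, 167 to 573 for 48 against 7/8 h, 35 to 103 for 48 against 24 h and 1 to 179 for TGF-β1 against DOC. The highest counts of set 2 albumin and of 48 against 7/8 h, 190 and 573, came without blockers replicate 4 and without the DOC array at 24 h. Blockers against sham had 1 gene without albumin replicate 1 or 3, blockers replicate 4 or sham replicate 1. For 48 against 7/8 h the count was 167 and 303 without the DOC arrays at 7 and 48 h, 230 without albumin at 8 h, and 172, 338 and 208 without TGF-β1 at 8, 24 and 48 h. For 48 against 24 h it was 93 and 53 without DOC at 7 and 24 h, 87, 65 and 91 without albumin at 8, 24 and 48 h, and 76, 35 and 42 without TGF-β1 at 8, 24 and 48 h. A lone sham was assumed to vary like the other groups, and the single sham of set 1 could not be left out.

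Among the lists of genes 2-fold changed in set 1, the list from the DOC 24 h array had −0.645 (fry p of 0.0579) for the higher genes with blockers against albumin, −0.68 (fry p of 0.0697) for the lower genes with albumin against sham and 0.48 (fry p of 0.128) for the lower genes with blockers against albumin. For these last, genes 2-fold lower at all 3 albumin times had 0.583 (fry p of 0.0539) and the TGF-β1 list 0.367 (fry p of 0.0554). Without 1 array the range was 0.385 to 0.804, and the call ended without blockers replicate 1 (0.644, fry p of 0.0504); the cause was not tested. Over genes with mean log2 above 7, correlations of DOC with albumin, DOC with TGF-β1 and albumin with TGF-β1 were 0.89, 0.733 and 0.842, and those of DOC, albumin and TGF-β1 at 24 h with set 2 were 0.672, 0.723 and 0.586. Without albumin replicate 2 the neuron list in blockers against albumin changed sides, from a median of 0.127 (adjusted p = 0.0418) to −0.008 (adjusted p = 0.775), with adjusted p down to 0.00265 without albumin replicate 1. Over the list results without 1 array, 517 stayed on their side of the threshold, 26 lost and 14 gained it, and 36 that passed in neither changed direction; the neuron list above was the 1 other. With an estimated correlation 131 list results stayed on their side of the threshold and 133 lost it. With the mean of probe sets 237 stayed, 11 lost and 8 gained it, and 8 that passed in neither changed direction. For named genes without 1 array, 7222 results stayed, 846 lost and 86 gained the threshold, 63 changed sign with the threshold passed in neither, and 0 that passed changed sign. The correlations did not settle whether replicate numbers pair the arrays of set 2. Those of the same number correlated at r = 0.223, 0.219 and 0.05 between albumin and blockers. Albumin replicates 1 and 2 correlated best with the blocker array of their own number, but albumin replicate 3 more closely with blockers replicate 4 (0.122). Between blockers and sham, arrays of the same number had 0.001 and −0.136. The main model has no pairing, and the replicate block gave 53 genes instead of 137 for albumin against sham. Signals near the floor limit folds: in the set 2 shams Socs3 had 2.34, Cxcl1 2.51 and Ccl2 3.62, so that their folds rest on background.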

Other observations

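The tests of time of day and of a glucocorticoid response and the counts over other splits were chosen before their results were seen, while the clock test with Bmal1 and Npas2 alone was run, and the genes Alas2, Brcc3-ps7 and, in set 2, Calca were chosen, only after the result was seen.

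Genes known to respond to glucocorticoids (Fkbp5, Pdk4) were lower at 24 h than at 7/8 h in set 1. Against time of day at collection speaks the gap between clock output genes and Bmal1, Npas2 and Clock at 48 against 24 h, which was 0.535, or 0.411 with Bmal1 and Npas2 alone, the 2 genes for which a bound of under 0.25 had been set beforehand. The same gap was −0.818 at 24 h against 7/8 h, or −0.79 with those 2 alone, past the 0.5 set beforehand, so that time of day stays open, though no clock gene passed. A glucocorticoid response at 7/8 h stays open as well, since 8 other targets had a median of −0.413 (6 of 8 below 0; camera p of 0.013, 0.264 with an estimated correlation), short of the −0.5 set beforehand. The agent and the time since surgery were not separated from either.

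Other splits of the same arrays were counted for each comparison of groups of at least 3. For blockers against albumin, the real split gave 2 genes, and 2 was also the highest among the others. Counting the real one, 2 of the 35 splits gave as many, so chance cannot be excluded. In set 1 each comparison has 10 splits, too few for a share under 0.05. The real split gave 80 genes for 24 against 7/8 h, 510 for 48 against 7/8 h, 141 for 48 against 24 h, 1 for albumin against DOC and 3 for TGF-β1 against DOC, with 0 the highest other and 1 of 10 splits as large in each. For TGF-β1 against albumin it gave 0, as did all 10 of 10.

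The signal of Brcc3-ps7 was 2.11 to 3.00 on the 3 DOC arrays and 7.01 to 8.63 on the other 7 of set 1. In set 2 Brcc3-ps7 was at 2.14 to 2.24 on albumin replicate 3 and blockers replicates 2 and 4, and at 8.48 to 9.72 on the other 6 arrays, both shams included, so that low values were not confined to DOC. Calca lay 0.84, 3.30 and 5.44 above sham with DOC at 7, 24 and 48 h, 0.91, 3.67 and 5.70 with albumin at 8, 24 and 48 h and 0.80, 4.10 and 5.26 with TGF-β1. In set 2 Calca averaged 10.38 with albumin, 7.07 with the blockers and 5.29 in sham. The red cell gene Alas2 lay 1.99 ± 0.72 above sham in set 2 albumin, 1.88 ± 0.37 in DOC and 2.41 ± 0.37 in albumin of set 1. Nr4a1 lay −2.75 ± 0.44, −2.38 ± 0.44 and −2.01 ± 0.44 from the set 1 sham with DOC, albumin and TGF-β1, and 0.25 ± 0.48 with set 2 albumin.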
